A study of Danio rerio with 4 samples.

How the data were processed

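RNA was measured in 4 libraries of zebrafish embryos, 1 library in each of 4 groups. The groups were wild-type embryos (WT) and maternal ybx1 mutant embryos (Mybx1), each at 0 and at 6 hours post fertilisation (hpf). Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase I and cleaned on RNeasy columns, ribosomal RNA was removed with a Ribo-zero kit, and libraries were made with a NEBNext RNA kit. Whether the kit or the counting kept strand was not given in the sources used here, so reads of a gene and of an overlapping antisense gene could not be told apart. How many embryos or clutches went into a library was also not given in the sources used here.

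The authors deposited 1 table of FPKM values (fragments per kilobase of gene and scaled to library size), with a column for each library and a line for each of 31870 gene identifiers. It held 0 columns of other samples. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and the genome build GRCz10, with no role given for any of them. The formula for the FPKM values, the annotation release and the treatment of reads that map to several genes were not given in the sources used here. FPKM values are shares of a library's reads, so a change in the total RNA of an embryo leaves no trace in them, and a gain in a few abundant transcripts lowers all others. This limits the comparisons across stages in particular, because the RNA content of an embryo may differ between stages.

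Low FPKM values of a gene were whole multiples of a common step, which whole reads would give. The library totals behind the FPKM values could therefore be recovered as whole numbers to within 0.00018 of a read. They were 7570070 for WT at 0 hpf, 6240685 for WT at 6 hpf, 7303656 for Mybx1 at 0 hpf and 6042830 for Mybx1 at 6 hpf. At these totals 97.7% of 2577 genes with low values had a whole-number length, against 49.5% at 2 times the totals. For each of the 25595 genes above 0 in any library, the smallest set of whole reads that gives all 4 values was taken. These smallest reads are lower limits and add up to between 88.8% and 93.3% of the library totals. The recovery was tested on simulated values of 5773 genes, where all 4 totals and the reads of 93.2% of genes were recovered exactly and 0 genes received more reads than were simulated.

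Differences between libraries were computed on log2(FPKM + 1), a scale that understates the change of genes with low values. With 1 library per group there is no replicate error, so no p-value was computed and every difference compares 2 libraries, not 2 populations of embryos. A gene was counted in a comparison when its mean FPKM over the libraries compared was at least 1, and called higher or lower when it was at least 2-fold apart. In the text, rose and fell are used only of genes past this 2-fold threshold. Folds of single genes are ratios of FPKM without the pseudocount of 1, with an exact (Clopper-Pearson, conditional binomial) 95% interval from the smallest whole reads. Because those reads are lower limits, the intervals are if anything too wide. For a gene with 0 reads in 1 of the libraries, the fold is a bound against the FPKM that 3 reads would give in that library. Such a bound leaves out the counting error of the other library, so the lower limit of a 95% counting interval lies below it. Intervals and bounds cover counting error only, since the reads carry no molecular identifiers.

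The count of genes past 2-fold was tested on simulated libraries in which 50 genes were changed at each size. Of genes changed 3-fold, 94.0% passed for WT at 6 against 0 hpf, 98.0% for Mybx1 at 6 against 0 hpf, 96.0% for the 0 hpf libraries and 88.0% for the 6 hpf libraries, with between 13803 and 15798 genes counted. In the same order 96.0%, 100%, 100% and 98.0% passed at 4-fold, and 100%, 98.0%, 100% and 100% at 8-fold. The count that counting noise alone gives was simulated in 20 draws per comparison, with both libraries drawn at their pooled rate.

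Gene symbols came from a table that pairs gene identifiers with symbols. A symbol was found for 26099 of 31870 identifiers (81.9%), and spelled as in the RefSeq gene table of assembly GRCz12tu where that table has it. In capitals are symbols given in their human form, and 4274 identifiers share a symbol with another. No coordinates are given because no annotation of the GRCz10 build was used here. Before the data were examined, 25 gene lists were fixed for oocyte and egg genes, maternal activators of the zygotic genome, first-wave zygotic genes, Nodal signalling and mesendoderm, the dorsal organizer, ventral and BMP signalling, neuroectoderm, the enveloping layer, the yolk syncytial layer, germ plasm, maternal ribonucleoproteins, mRNA decay, the unfolded protein response, apoptosis and stress, heat shock, the cell cycle, epiboly and adhesion, ribosomal proteins, translation factors, proteasome subunits, mitochondrial-encoded transcripts, histones, and markers of ovarian follicle, of blood, liver and muscle, and of testis. Of their 657 members 572 were matched. Some genes sit in several lists, such as ved among first-wave and ventral genes, so the lists are not independent of each other. The 5 lists of protein and transcript families were filled by symbol patterns, from which a few look-alike symbols that name other proteins were left out once the symbols were seen. None was left out of the proteasome list, which may therefore hold such look-alikes. The histone pattern was also widened beyond the one fixed in advance, and so took in symbols such as h1m and H3-3B. The list median is the median log2 difference over members with a mean FPKM of at least 1. It is given with a 95% bootstrap interval over members (2000 draws) and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test.

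The genes named in the text follow a rule fixed in advance. For each comparison it takes the 8 largest rises and 8 largest falls among genes with a symbol and an FPKM of at least 10 in the higher library, small RNAs left out, up to 4 members of each list with an FPKM of at least 5, and 12 genes fixed by name, which are ybx1, pou5f3, nanog, sox19b, ndr1, ndr2, lft1, gsc, chrd, tbxta, hspa5 and xbp1. Any gene outside this rule is marked as chosen after its values were seen. Maternal clearance was read on genes with an FPKM of at least 5 at 0 hpf in both genotypes and at least 4-fold lower at 6 hpf in WT. Zygotic activation was read on genes under 0.5 FPKM at 0 hpf in both genotypes and at 5 or more at 6 hpf in WT. Because selection in WT favours a larger change there, both were repeated with genes selected in Mybx1.

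Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 5, a 4-fold threshold, median-ratio scaling (on genes above an FPKM of 5 in all 4 libraries), rescaling to the same sum in every library (TPM), and TPM without mitochondrial, ribosomal, small RNA and histone genes. Added after the data were seen were the count of genes whose 95% counting interval lies wholly beyond 2-fold, list matching that ignores the paralog letter, and list medians over time taken over members counted in either genotype, which the report uses for the zygotic lists in Mybx1 and for the plot of list medians. Small RNAs, taken as 1128 identifiers by symbol and biotype, stayed in the counts of genes. The work used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.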

Results

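The series holds total RNA, depleted of ribosomal RNA, from WT and Mybx1 zebrafish embryos at 0 and 6 hpf, with 1 library per group. The labels name the mutated gene as ybx1, which encodes a cold-shock domain protein that binds maternal mRNA, and call the mutation maternal. The 0 hpf libraries hold the RNA laid down in the egg, and by 6 hpf, at the start of gastrulation, a WT embryo has replaced much of it with transcripts of its own genome. The comparisons ask how far this turnover took place in embryos of mutant mothers and how the eggs themselves differed. Between 6042830 and 7570070 reads lay behind the FPKM values of a library, and between 13213 and 15207 genes reached an FPKM of 1. No difference below has a replicate check.

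The mutated gene itself was low in both libraries labelled Mybx1. The FPKM of ybx1 was 338 in WT and 11.9 in Mybx1 at 0 hpf, 28.5-fold lower (95% counting interval 23.2 to 35.4). At 6 hpf it was 2287 in WT and 54.2 in Mybx1, 42.2-fold lower (38.0 to 47.0). Within each genotype the level of ybx1 rose from 0 to 6 hpf, 6.76-fold in WT (6.49 to 7.04) and 4.57-fold in Mybx1 (3.63 to 5.79).

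In WT, transcripts of the egg gave way to those of the gastrula between 0 and 6 hpf. Of 15031 genes counted, 3637 rose and 6183 fell. All 19 counted oocyte and egg genes fell, and all counted members of the lists for first-wave zygotic genes (16), Nodal signalling and mesendoderm (22), the dorsal organizer (11), ventral and BMP signalling (12), neuroectoderm (9) and the yolk syncytial layer (11) rose. The filter leaves out members near 0 at both stages, so a counted gene near 0 at 0 hpf had to rise. In the same order 16, 24, 12, 13, 9 and 14 members of these zygotic lists were matched. Of the 18 counted genes of the enveloping layer, the outer epithelium of the early embryo, 17 rose, and epcam, an adhesion molecule named after its values were seen, fell from 717 to 342 FPKM.

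Among oocyte genes, btg4, an adaptor of the deadenylase complex, fell 89.4-fold (60.0 to 139.8), mos, the kinase that holds the egg in meiosis, fell 86.5-fold (53.9 to 148.8), and org fell 74.6-fold (59.2 to 95.2). The claudin gene cldng fell 93.9-fold (76.6 to 116.4), and lipg, an endothelial lipase, had the largest fall of the named genes, 135.8-fold (96.6 to 197.5). The median change of the oocyte list was -4.20 (-5.57 to -3.26). Germ plasm genes fell in 10 of 13 cases, among them buc, which organises the germ plasm, 63.5-fold (52.2 to 78.1), and ca15b, 72.0-fold (55.4 to 95.5). The maternal linker histone h1m fell 21.3-fold (19.2 to 23.5) and h2af1al fell 65.6-fold (53.8 to 80.7). Of the maternal activators of the zygotic genome, nanog fell 6.70-fold (6.14 to 7.33) and sox19b 7.61-fold (6.99 to 8.29), whereas pou5f3 rose 4.16-fold (3.99 to 4.34). Of the 31 unfolded protein response genes 19 fell and 2 rose, with hspa5, the chaperone BiP, 5.06-fold lower (4.85 to 5.27).

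Among the genes that rose in WT, several had 0 reads at 0 hpf. Against the level of 3 reads in that library, the small heat shock gene hspb1 was at least 3578-fold higher at 6 hpf, the keratin gene krt5 at least 1724-fold, the T-box gene tbxta, required for the notochord and tail, at least 1256-fold, and chrd, an antagonist of BMP, at least 1474-fold. The organizer gene gsc rose 46.3-fold (20.9 to 127.5), lft1, an inhibitor of Nodal, rose 543-fold (97.0 to 21510), and ccnd1, a cyclin of the first gap phase, rose 281-fold (197 to 417). The median changes were 6.14 for the first-wave list, 4.70 for Nodal and mesendoderm, 4.24 for the organizer, 4.57 for ventral genes, 5.64 for neuroectoderm, 6.28 for the enveloping layer and 5.47 for the yolk syncytial layer, each at percentile 100 of matched random lists. With the genes of 0 reads set at the level of 3 reads and no pseudocount, these medians were 8.41, 6.66, 5.53, 6.58, 8.48, 8.17 and 7.26. Of 82 ribosomal protein genes 56 rose and none fell, with a median of 1.19 (1.1 to 1.40), and eef1a1l1, a translation elongation factor, rose 10.6-fold (10.4 to 10.9). Histones rose in 11 and fell in 3 of 19 cases, and heat shock genes rose in 8 and fell in 1 of 11. Other medians were 0.88 for the apoptosis and stress list, 0.81 for maternal activators, 0.70 for epiboly and adhesion, -0.82 for mRNA decay genes and -1.20 for testis markers. Of markers of blood, liver and muscle only cahz, a carbonic anhydrase, was counted, with 0 reads at 0 hpf and 15.4 FPKM at 6 hpf.

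The median of all genes was -0.57 in this comparison, -0.80 with TPM and 0.07 with median-ratio scaling. Under the latter 5155 genes rose and 4367 fell, so rises made up 54.1% of the calls in place of 37.0%. The medians of the cell cycle list (-0.31), the maternal ribonucleoprotein list (-0.32), the mitochondrial-encoded transcripts (-0.12) and the proteasome subunits (-0.07) turned positive with that scaling, and the translation factors (0.18) turned negative with TPM.

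**Figure D1:**
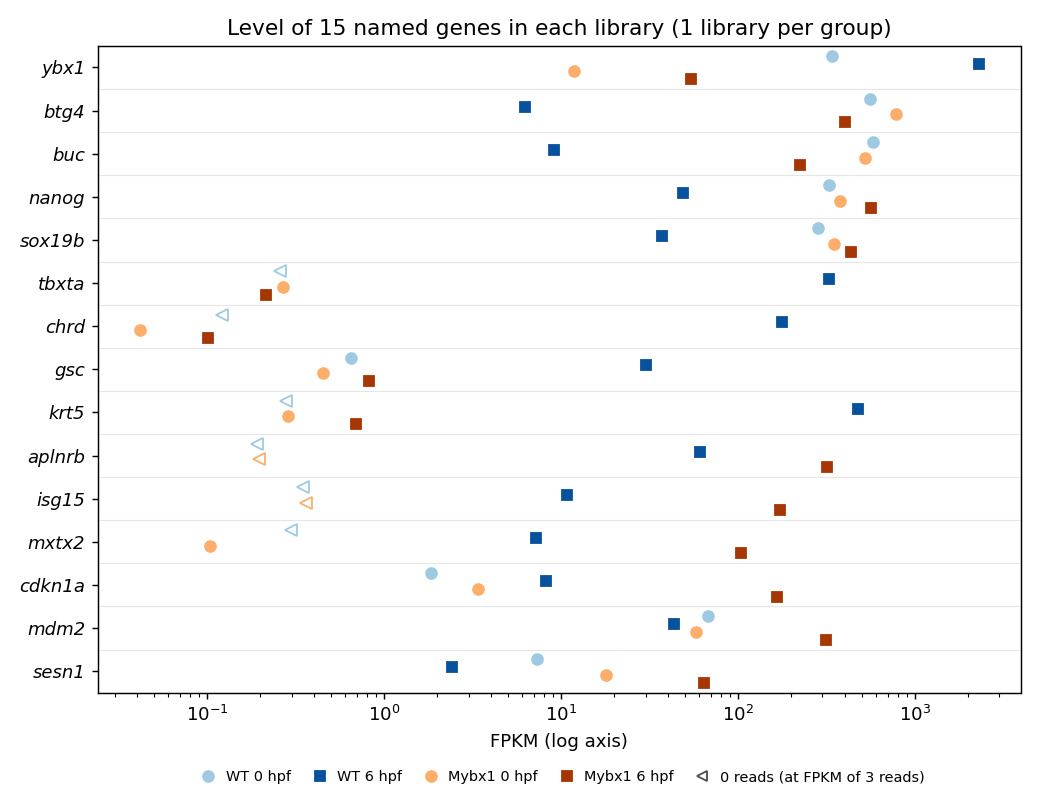
FPKM (log axis) of 15 named genes in the 4 libraries, 1 point per library, with open triangles at the FPKM of 3 reads where a library had 0 reads. At 6 hpf btg4 stood at 6.22 in WT and 401 in Mybx1, and tbxta at 325 in WT and 0.22 in Mybx1.

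In Mybx1, most of this turnover was missing. Of 14790 genes counted, 1134 rose and 1050 fell from 0 to 6 hpf, and only 102 fell at least 4-fold, against 3004 in WT. Several egg transcripts stayed abundant, as seen in genes chosen in part after their values were seen (h1m, cldnd and eve1): h1m went from 1017 to 904 FPKM, btg4 from 783 to 401 and cldnd, a claudin of the egg, from 2508 to 1503. Some genes of the germ layers stayed low: tbxta was at 0.27 and 0.22 FPKM, chrd at 0.042 and 0.10, and eve1, a ventral homeobox gene, had 0 reads at both stages. Counting noise alone gave on average 77.1 genes higher and 83.6 lower. Among genes with a mean FPKM of at least 5, 410 rose and 863 fell, so rises made up 32.2% of the calls in place of 51.9%. With median-ratio scaling 1131 rose and 754 fell.

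Some zygotic genes were nevertheless switched on in Mybx1, to levels above those of WT in several cases. The filter on mean FPKM leaves out a gene that stays near 0 at both stages, so the lists of zygotic genes were read in Mybx1 over all members counted in either genotype. Of 16 first-wave genes 15 rose, with a median of 3.49 (1.90 to 5.02), and foxd5, a forkhead gene named after its values were seen, had 0 reads at both stages. The apelin receptor gene aplnrb rose from 0 reads to 316 FPKM (at least 1607-fold), against 61.2 in WT at 6 hpf. The interferon-stimulated gene isg15 rose from 0 reads to 172 FPKM (at least 479-fold), against 10.8 in WT, and mxtx2, a regulator of the yolk syncytial layer, rose 1004-fold (180 to 39720) to 104 FPKM, against 7.25 in WT. The homeobox gene irx7 reached 120 FPKM in both genotypes. Rises short of the WT level included apoeb, an apolipoprotein gene (0.66 to 211 FPKM, 1971 in WT), krt18a.1 (0.26 to 77.0 FPKM, 2042 in WT) and hspb1 (1.07 to 66.2 FPKM, 1854 in WT). In the other lists 11 of 22 Nodal and mesendoderm genes rose, 4 of 11 organizer genes, 4 of 12 ventral genes, 4 of 9 neuroectoderm genes, 7 of 18 enveloping layer genes and 8 of 11 yolk syncytial layer genes, and none fell. The median changes in that order were 0.94, 0.32, 0.42, 0.22, 0.35 and 1.60. Over the members counted in Mybx1 alone, a set that favours genes that rose, they were 1.73, 2.01, 0.62, 2.51, 3.03 and 2.71, and 3.93 for the first-wave list. With genes of 0 reads at the level of 3 reads, no pseudocount and genes of 0 reads at both stages taken as unchanged, the medians over all members were 1.27, 1.27, 0.46, 1.01, 1.27 and 2.86, and 5.50 for the first-wave list.

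Of 13 genes of the apoptosis and stress list 6 rose in Mybx1 and 1 fell, ddb2 (-1.22), a DNA damage binding protein named after its values were seen. In Mybx1 the cell cycle inhibitor cdkn1a rose 49.4-fold (32.7 to 78.3) and foxo3b, a forkhead transcription factor, 25.8-fold (17.9 to 38.6). There phlda3, an inhibitor of Akt signalling, rose 16.2-fold (10.7 to 25.7) and bbc3, the cell death effector Puma, 12.6-fold (9.87 to 16.2). In WT 6 members rose and 3 fell. Rises in WT were 4.48-fold for cdkn1a (2.39 to 9.01), 5.37-fold for bbc3 (2.97 to 10.4) and 41.2-fold for phlda3 (6.92 to 1676), the last from 0.089 FPKM. The stress response gene GADD45A rose 287-fold in Mybx1 (112 to 1057), but its symbol is shared by several genes and its identity is uncertain. The list median was 0.98 (0.63 to 3.23) in Mybx1, at percentile 100, and 0.88 (-0.84 to 1.47) in WT.

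The oocyte list had a median of -0.85 (-1.26 to -0.21) in Mybx1, short of 2-fold, against -4.15 over the same members in WT. While 11 of 20 members stayed within 2-fold, 9 fell, among them org, 5.44-fold lower (5.09 to 5.81), mos, 3.43-fold (3.08 to 3.82), and slbp2, a histone mRNA binding protein of the egg, 3.18-fold (2.96 to 3.42). Germ plasm genes fell in 4 of 13 cases, with ca15b 3.15-fold (2.95 to 3.36) and dazl, a translational regulator of germ cells, 3.73-fold lower (3.31 to 4.23). Among the largest falls were those of mrpl53, a mitochondrial ribosomal protein gene, 31.7-fold (10.6 to 156), ndufa3, a subunit of respiratory complex I, 12.1-fold (6.38 to 25.7), lamtor3, a scaffold of the lysosomal Ragulator complex, 10-fold (6.11 to 17.5), and kpna2, an importin, 6.51-fold (6.03 to 7.02). The activators nanog (375 to 564 FPKM), sox19b (349 to 432) and pou5f3 (219 to 276) stayed within 2-fold. So did 81 of 82 ribosomal protein genes (median -0.19), 65 of 67 translation factors (-0.08), 48 of 50 proteasome subunits (-0.17), 19 of 21 histones (0.37), 13 of 13 mitochondrial-encoded transcripts (0.03), 24 of 25 mRNA decay genes (-0.01), 18 of 19 maternal ribonucleoprotein genes (0.10) and 7 of 7 maternal activators (0.33). Of all 14790 counted genes 7.7% rose and 7.1% fell, and some lists changed in larger shares. Of 26 cell cycle genes 4 rose, 5 fell and 17 stayed within 2-fold (-0.01). Of 8 heat shock genes 1 rose, 2 fell and 5 stayed (0.03). Of 29 unfolded protein response genes 1 rose, 7 fell and 21 stayed (-0.28). Of 16 epiboly and adhesion genes 3 rose, none fell and 13 stayed (0.27). The medians of the cell cycle, mRNA decay, translation factor and testis lists (-0.02 for the last) turned positive with median-ratio scaling. Over members counted in either genotype the medians of heat shock (-0.14) and mRNA decay genes (0.01) changed sign. With median-ratio scaling the median of all genes moved from -0.08 to 0.05.

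Across 15376 genes the changes in the 2 genotypes were correlated (Pearson r 0.58, Spearman rho 0.55, across genes, which are not independent replicates), but the slope of the Mybx1 change on the WT change was 0.24. Of 3283 genes that rose in WT, 997 rose in Mybx1, 2248 stayed within 2-fold and 38 fell. Of 6285 genes that fell in WT, 774 fell in Mybx1, 5494 (87.4%) stayed within 2-fold and 17 rose. The Mybx1 library at 6 hpf correlated more closely with the WT library at 0 hpf (r 0.87) than with that at 6 hpf (r 0.65), and most closely with the Mybx1 library at 0 hpf (r 0.92). These 2 developmental changes share no library.

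**Figure D2:**
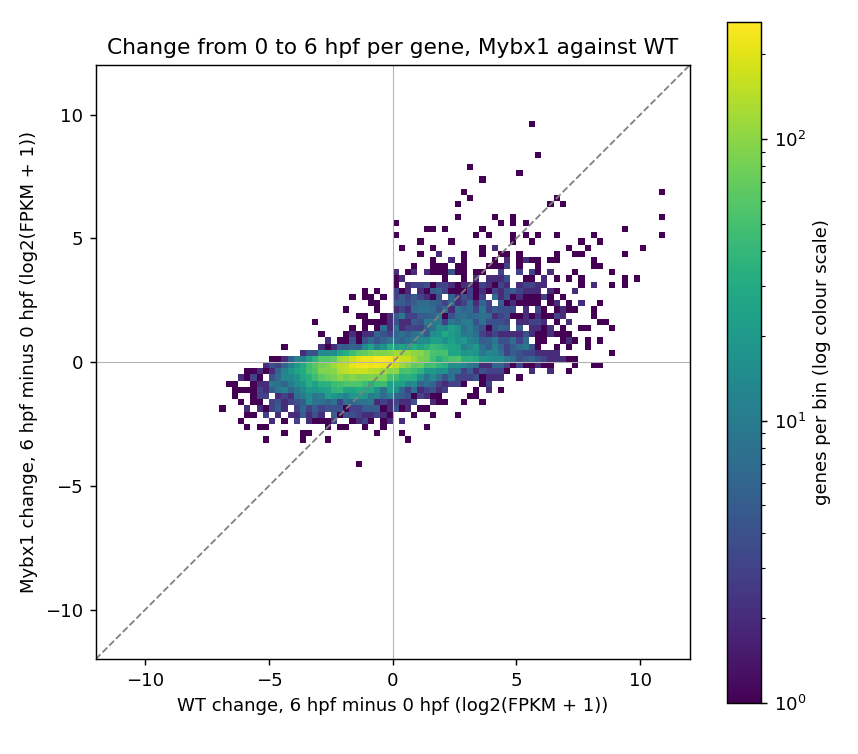
Change from 0 to 6 hpf in Mybx1 (y axis) against that in WT (x axis), in log2(FPKM + 1), for 15376 genes, with colour giving the number of genes per square on a log scale and a dashed line of equal change. The changes in Mybx1 spread less (SD 0.86) than those in WT (SD 2.07), with a slope of 0.24.

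The genes set by maternal clearance and zygotic activation in WT show the same difference. Of 2779 maternal genes that fell at least 4-fold in WT, 56 (2.0%) did so in Mybx1. Their median change was -2.76 in WT and -0.42 in Mybx1 (-0.45 to -0.40), and their median FPKM went from 33.3 to 3.25 in WT and from 33.3 to 22.7 in Mybx1. Of 771 zygotic genes that reached an FPKM of 5 in WT, 132 (17.1%) did so in Mybx1 and 250 stayed under 0.5. Their median change was 3.74 in WT and 0.95 in Mybx1 (0.83 to 1.07), and the Mybx1 value depended on the pseudocount, at 2.76 with 0.1 and 0.26 with 5. Selected in Mybx1 instead, 89 genes fell at least 4-fold and had a median change of -2.68 in WT, and 204 genes reached an FPKM of 5, of which 132 (64.7%) did so in WT.

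The 0 hpf libraries of the 2 genotypes were alike in most genes. Of 13811 genes counted, 1222 were higher and 926 lower in Mybx1, against 38.6 and 39.0 from counting noise, and the correlation across genes was 0.94. The side with more genes depended on low values, since 524 were higher and 613 lower among genes with a mean FPKM of at least 5. Transcripts of the unfolded protein response were among those lower in Mybx1. Of 29 counted unfolded protein response genes 7 were lower and none higher, with a median of -0.57 (-0.80 to -0.26) below all 10000 random lists. They included trib3, a pseudokinase induced by stress, 11.9-fold lower (8.35 to 17.4), calr3b, a calreticulin, 4.67-fold (4.15 to 5.28), dnajc3a, an inhibitor of the kinase PERK, 4.15-fold (3.23 to 5.39), and pdia4, a protein disulfide isomerase, 2.71-fold (2.5 to 2.93), whereas hspa5 was at 896 FPKM in WT and 554 in Mybx1.

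Of 68 translation factor genes 61 were within 2-fold, 7 were lower and none higher, with eif5, which acts on start codon selection, at 232 FPKM in WT and 44.3 in Mybx1 (5.23-fold lower, 4.66 to 5.90), and 2 genes that share the symbol EIF4G2, 10.1-fold (8.84 to 11.6) and 4.99-fold lower (4.40 to 5.67), which cannot be assigned to either copy with certainty. Among the genes furthest below WT besides ybx1 were the zinc finger gene znf1035, 100-fold (71.1 to 146), tmprss15, 209-fold (57.5 to 1730), SMCR8, 171-fold (46.9 to 1416), sona, 26.9-fold (17.6 to 43.2), prr14, 20.5-fold (14.8 to 29.4), and tasor2, 18.9-fold (13.9 to 26.1). Lower members of other lists were the egg coat gene zp3b, 2.93-fold (2.73 to 3.14), the piwi gene piwil1, 2.82-fold (2.39 to 3.34), and ythdf3, a reader of methylated mRNA, 4.80-fold (3.83 to 6.08).

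Higher in Mybx1 at 0 hpf were gas5, a host gene of small nucleolar RNAs, at 31.7 FPKM against 0.17 (191-fold, 33.8 to 7573), TBR1, a T-box gene of the brain, 106-fold (55.5 to 232), gata2b, 66.9-fold (32.2 to 167), AANAT, an enzyme of melatonin synthesis, 35.9-fold (18.7 to 79.3), pmp22a, 58.4-fold (19.6 to 286), and bdnf, a neurotrophin with 0 reads in WT, at least 37.3-fold. The mesoderm gene msgn1 was 87.1-fold higher (23.7 to 725), cyp26a1, which breaks down retinoic acid, 9.42-fold (7.65 to 11.7), the oocyte transcription factor figla 8.56-fold (5.54 to 13.8) and mych, a Myc relative, 4.56-fold (3.74 to 5.59). Of 13 apoptosis and stress genes 4 were higher and none lower, among them pmaip1, the cell death effector Noxa, 7.84-fold (4.64 to 14.2), and sesn1, a sestrin, 2.48-fold (2.05 to 3.03). The apoptosis and stress list median was 0.62 (-0.02 to 1.2).

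The medians of other lists at 0 hpf were 0.00 for oocyte genes (2 of 20 higher, 2 lower), -0.16 for germ plasm, 0.30 for maternal activators, 0.01 for maternal ribonucleoproteins, -0.11 for mRNA decay genes, 0.10 for cell cycle, -0.04 for heat shock, -0.01 for epiboly and adhesion, -0.13 for ribosomal proteins (percentile 0 of matched random lists), -0.10 for the proteasome, 0.05 for histones and 0.39 for mitochondrial-encoded transcripts (percentile 99.7). Those for oocyte genes and maternal ribonucleoproteins turned slightly negative with TPM. Of markers of the ovarian follicle only hsd3b2 and cyp17a1, enzymes of steroid synthesis, were counted, at 107 and 82.5 FPKM in Mybx1 against 25.6 and 48.9 in WT, and hsd3b2 was 4.17-fold higher (3.63 to 4.80). Of the testis markers 4 were counted and all stayed within 2-fold (median -0.21), and of those of blood, liver and muscle 1 was.

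At 6 hpf the 2 genotypes differed in most of the genes that mark the stage. Of 15790 genes counted, 6035 were higher and 3284 lower in Mybx1. All 11 organizer genes and all 12 ventral genes were lower, as were 20 of 22 Nodal and mesendoderm genes, 17 of 18 enveloping layer genes, 12 of 16 first-wave genes, 10 of 12 yolk syncytial layer genes and 7 of 9 neuroectoderm genes. These zygotic lists share some members, so their counts are not independent. Higher were 16 of 20 oocyte genes, 9 of 13 germ plasm genes and 10 of 13 apoptosis and stress genes, with none of these 3 lists holding a lower member.

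Among the lower genes, tbxta stood at 325 FPKM in WT and 0.22 in Mybx1 (1504-fold, 416 to 12430), krt5 at 479 and 0.70 (688-fold, 316 to 1876), chrd at 178 and 0.10 (1765-fold, 488 to 14580), krt92 at 351 and 1.03 (341-fold, 173 to 790) and gsc at 30.2 and 0.82 (37.0-fold, 16.7 to 102). The ventral gene eve1 stood at 121 FPKM in WT and had 0 reads in Mybx1 (at least 311-fold lower). The endoderm regulator sox32 was 196-fold lower (89.8 to 535), the neural gene sox2 164-fold, mttp, which loads lipoproteins, 180-fold (126 to 270), and ccnd1 80.2-fold (64.7 to 101). The median differences were -3.43 for first-wave genes, -3.22 for Nodal and mesendoderm, -3.24 for the organizer, -3.18 for ventral genes, -3.24 for neuroectoderm, -4.74 for the enveloping layer and -3.11 for the yolk syncytial layer. With genes of 0 reads at the level of 3 reads and no pseudocount they were -3.53, -4.32, -4.12 and -3.70 for the first 4 of these lists, -5.75 for the enveloping layer and -3.16 for the yolk syncytial layer. Neuroectoderm had no gene of 0 reads and stood at -3.5 without the pseudocount. The Nodal ligand genes did not go together, since ndr2 was 4.02-fold lower (3.01 to 5.46) while ndr1 stood at 3.62 FPKM in WT and 4.99 in Mybx1.

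Among the higher genes, btg4 stood at 6.22 FPKM in WT and 401 in Mybx1 (64.5-fold, 43.1 to 101), lsm14b, an mRNP protein of the egg, at 8.57 and 394 (46.0-fold, 37.3 to 57.2), buc at 9.16 and 224 (24.5-fold, 20 to 30.1), nanog at 48.5 and 564 (11.6-fold, 10.7 to 12.7) and sox19b at 37.3 and 432 (11.6-fold, 10.7 to 12.6). The medians were 3.77 for oocyte genes (2.95 to 4.18) and 2.29 for germ plasm (0.32 to 3.93). The steroid enzyme gene cyp17a1 was at 75 FPKM in Mybx1 and 1.66 in WT, and hsd3b2 at 90.3 and 84.9. The apoptosis and stress list had a median of 2.75 (1.67 to 2.98), with cdkn1a 20.2-fold (15.1 to 27.6), sesn1 26.6-fold (19.4 to 37.2), bbc3 12.6-fold (9.75 to 16.7) and phlda3 9.78-fold higher (6.86 to 14.4).

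Ribosomal protein genes were lower in 75 of 82 cases (median -1.61, -1.66 to -1.47), with rpl34 5.67-fold lower (4.89 to 6.59), and eef1a1l1 was 8.85-fold lower (8.63 to 9.07). Heat shock genes were lower in 7 of 12 cases, with hsp90ab1 4.97-fold lower (4.81 to 5.13) and hspe1, a mitochondrial chaperonin, 6.00-fold (5.08 to 7.13). The unfolded protein response list split into 13 higher and 8 lower genes of 31, with eif2ak3, the kinase PERK, 6.6-fold higher (5.63 to 7.77) and dnajc3a 10.4-fold lower (5.05 to 24.9), and xbp1 at 206 FPKM in WT was 2.48-fold lower (2.28 to 2.69). Other medians were -0.53 for maternal activators, 0.11 for maternal ribonucleoproteins, 0.49 for mRNA decay genes, 0.44 for cell cycle, -0.58 for epiboly and adhesion, -0.39 for translation factors, -0.20 for the proteasome, -0.63 for histones, 0.36 for mitochondrial-encoded transcripts and 0.62 for testis markers. Of these, the cell cycle, ribonucleoprotein and mitochondrial medians turned negative with median-ratio scaling and that of the proteasome turned positive with TPM. Genes of the keratin, histone, hsp70 and hsp90 families have close copies, and their single values are uncertain where reads could be shared.

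The median of all genes was 0.49 in this comparison, 0.71 with TPM and 0.00 with median-ratio scaling. Under the latter 4625 genes were higher and 4722 lower, so higher genes made up 49.5% of the calls in place of 64.8%. The difference between the 2 developmental changes gave a similar picture, with 5692 genes higher and 2866 lower in Mybx1 of 15376 counted, or 4184 and 4155 with median-ratio scaling, where higher genes made up 50.2% of the calls in place of 66.5%. The median of all genes then moved from 0.52 to 0.07. The largest differences of change were those of krt5 (-8.51), tbxta (-8.41) and HSP90AA1 (-8.26) on the lower side, and h2af1al (5.62), ripor3 (5.40) and btg4 (5.31) on the higher side.

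**Figure D3:**
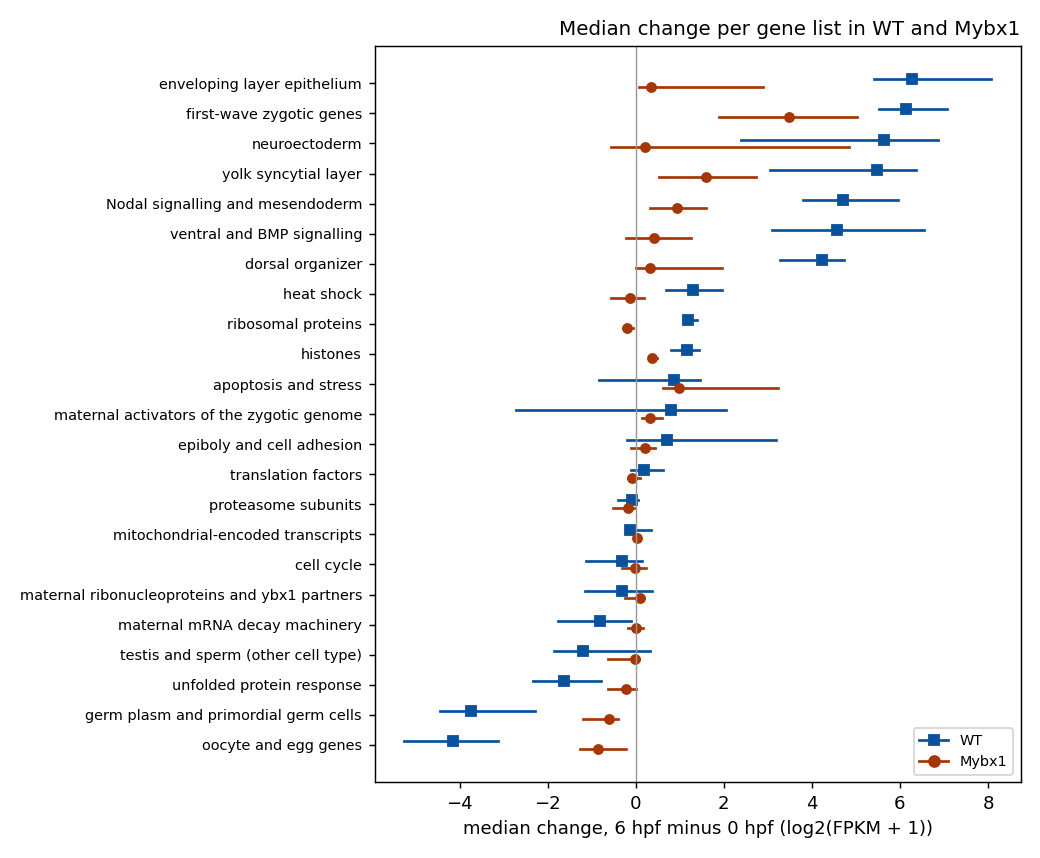
Median change from 0 to 6 hpf, in log2(FPKM + 1), of each gene list with at least 3 members counted in either genotype, over the same members in WT (squares) and Mybx1 (circles), with 95% bootstrap intervals over members as lines. The enveloping layer list stood at 6.28 in WT and 0.35 in Mybx1, and the oocyte list at -4.15 and -0.85.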

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

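All tests in this part were chosen after the result was seen. The change from 0 to 6 hpf went opposite ways in the 2 genotypes for 2 named genes that were at least 2-fold apart in each genotype and for 1 list whose bootstrap interval excluded 0 in each, and the difference was not tested, since each genotype has 1 library per stage. The sestrin gene sesn1 fell in WT (-1.27) and rose in Mybx1 (1.78), a difference of 3.05. The chaperonin gene hspe1 rose in WT (1.63) and fell in Mybx1 (-1.57), a difference of -3.20. The ribosomal protein list had a median of 1.19 in WT and -0.19 in Mybx1, a difference of -1.38, although 81 of 82 genes stayed within 2-fold in Mybx1 and the Mybx1 median moved to -0.05 with median-ratio scaling.

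The Mybx1 library at 6 hpf held high levels of egg transcripts and low levels of most zygotic transcripts. A mislabelled second 0 hpf library is excluded by the first-wave list, whose median change in Mybx1 was 3.49 (1.90 to 5.02) over all 16 members counted in either genotype. A mixture of unchanged egg RNA with WT-like 6 hpf RNA cannot put a zygotic gene above its WT level, yet of 1929 genes under 0.5 FPKM at 0 hpf in both genotypes 94 had a counting interval wholly above 2-fold the WT level, against 847 wholly below 0.5 of it, which excludes the mixture as the whole cause. Scaling is excluded as the whole cause, because the median gap between the changes in the 2 genotypes was 3.18 (2.17 to 3.56) for the 20 oocyte genes and -4.09 for the first-wave list with median-ratio scaling. A share of unchanged egg RNA in the library stays open as a part of the cause, since the number of embryos in it was not given. The genotype remains as a hypothesis, together with any difference between clutches or in handling, which the design cannot separate from it.

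Genes of the apoptosis and stress list were higher in Mybx1 than in WT at 6 hpf in 10 of 13 cases. Scaling is excluded as the whole cause, since the list median was 2.30 (1.2 to 2.55) with median-ratio scaling. Maternal transcripts kept in Mybx1 would leave the list at or below its 0 hpf level there, yet its median change from 0 to 6 hpf in Mybx1 was 0.98 (0.63 to 3.23) over all 13 members, so they are excluded as the whole cause. They stay open as a part of it, since casp8 (-2.05) and ddb2 (-3.43) fell in WT and are higher in Mybx1 at 6 hpf. At 0 hpf 4 of the 13 genes were already higher in Mybx1 and none lower, with a list median of 0.62 (-0.02 to 1.2). The change from 0 to 6 hpf was at least 2-fold higher in Mybx1 than in WT for 9 genes and lower for none. The median difference of changes was 1.95 (-0.21 to 3.04), an interval that includes 0. A difference already present at 0 hpf therefore also stays open as a part of the cause. A response of the embryos to damage or to arrest is a candidate explanation that was not tested.

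Between the 0 hpf libraries, 416 genes were at least 4-fold apart. Of the 191 lower in Mybx1, 64.9% were also at least 2-fold lower at 6 hpf, against at most 19.4% in 1000 draws of genes matched on expression, and of the 225 higher, 69.8% were also higher at 6 hpf, against at most 51.6%. An accident of the 0 hpf libraries alone is therefore excluded for these sets. A difference of clutch or handling shared by both libraries of a genotype would also persist to 6 hpf, so it stays open. Of the 416 genes, 59.9% (55.0 to 64.6) lay on other chromosomes than ybx1. This excludes, as the whole cause, a linked haplotype that acts only on genes of its own chromosome. A linked variant that acts on genes of other chromosomes stays open, because the place of the genes cannot test it. An effect of a linked haplotype on genes of its own chromosome stays open as a part of the cause. On the chromosome of ybx1 lay 5.7% of the placed genes (3.2 to 9.2), against 4.4% of all counted genes. Only 63.5% could be placed by symbol, fewer than the 80% the check needs. A difference in strain background cannot be told apart from the mutation, because the strain and parents of the embryos were not given in the sources used here.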

How the results depend on the processing

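No paired analysis was possible because each group holds 1 library and the labels give no replicate numbers. No named gene past 2-fold reversed its direction under a scaling, pseudocount or filter it was run under (510 values each, and 449 under TPM without abundant genes, which leaves genes out). For comparisons of 2 libraries this was fixed in advance and gives no support. A pseudocount or filter cannot turn the sign of such a difference, and each scaling moved values by less than 2-fold. Of the list medians whose interval excluded 0 only 1 reversed, the mitochondrial-encoded transcripts in Mybx1 against WT at 6 hpf, at -0.15 with median-ratio scaling. With that scaling 22 other list medians left their bootstrap interval, with TPM 9, and 15 and 16 did so with pseudocounts of 0.1 and 5. Matching lists without the paralog letter, also added after the data were seen, moved 0 of 110. Reading lists over members counted in either genotype, the last alternative added after the data were seen, left all 46 medians over time within their intervals, although that of the enveloping layer in Mybx1 went from 3.03 to 0.35. The cause of the changes below was not tested, except that a higher filter and a higher threshold leave fewer genes by construction.

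In the order WT over time, Mybx1 over time, the 0 hpf libraries, the 6 hpf libraries and the difference of changes, a 4-fold threshold left 2013, 565, 225, 2632 and 2244 genes higher and 3004, 102, 191, 1362 and 1361 lower. A pseudocount of 5 left 2233, 502, 358, 3863 and 3699 higher, and 550, 439, 1991 and 1870 lower in the last 4. A mean FPKM of at least 5 left 2003, 410 and 524 higher in the first 3, and 613, 2085 and 1623 lower in the last 3. Intervals wholly beyond 2-fold, an alternative added after the data were seen, held for 531 lower genes in Mybx1 over time and for 746 higher and 610 lower genes at 0 hpf.

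For ybx1 the rise in WT was 3.41 with median-ratio scaling, 2.49 with TPM and 2.65 with TPM without abundant genes, and the rise in Mybx1 was 1.81 with a pseudocount of 5. Its difference between genotypes was -4.35 at 0 hpf with a pseudocount of 5, and -5.89 with median-ratio scaling and -5.15 with TPM at 6 hpf. The median change of maternal clearance genes in Mybx1 was -0.45 with a pseudocount of 5, -0.35 with median-ratio scaling, -0.36 with TPM without abundant genes and -0.58 for falls of at least 8-fold, and genes selected in Mybx1 had -2.68 in WT. That of zygotic activation genes was 2.76 and 0.26 with pseudocounts of 0.1 and 5, 1.25 with TPM, 1.26 with TPM without abundant genes and 1.18 from an FPKM of 10, and genes selected in Mybx1 had 3.98 in WT. Depth limits what can be said of genes near 0, since 3 reads of a 1 kb gene amount to between 0.40 and 0.50 FPKM.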

Other observations

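The test in this part was chosen after the result was seen, and all genes named here were chosen after their values were seen, except where the rule for named genes took them. Transcripts of RNA polymerase III were left out of the named genes of the report. The RNA rn7sk, which holds the elongation factor P-TEFb in check, rose 96.9-fold in WT (89.4 to 105.3), from 244 to 23620 FPKM, and 105.9-fold in Mybx1 (91.5 to 123.2), from 77.8 to 8238 FPKM. The RNA of the enzyme RNase MRP, rmrp, rose 3.22-fold in WT and 2.02-fold in Mybx1 (1.97 to 2.06), and rpph1, the RNA of RNase P, rose 3.42-fold in WT, while in Mybx1 it went from 2958 to 5229 FPKM. The libraries were made from fragments of total RNA, and whether size selection bears on the levels of such short RNAs was not tested.

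In Mybx1, 203 genes rose at least 4-fold and stood at least 2-fold above WT at 6 hpf. Besides the apoptosis and stress and the first-wave genes they held phlda2 (0.52 FPKM in WT and 14.0 in Mybx1 at 6 hpf), the immune genes ftr22 (9.75 and 133.7) and mhc2daa (4.54 and 53.4), and FOS, a subunit of AP-1 (0.71 and 10.6). Both immune genes were already higher in Mybx1 at 0 hpf, ftr22 at 21.4 FPKM against 3.55 in WT and mhc2daa at 10.4 against 2.91. Among the 38 genes that rose in WT and fell in Mybx1 were snrpf (30.9 to 93.5 FPKM in WT and 68.5 to 22.3 in Mybx1) and snrpg (50.2 to 150.2 and 72.3 to 27.3), core proteins of the spliceosome, and nqo1 (11.4 to 50.6 and 19.8 to 8.23), an oxidoreductase. Among the 17 that went the other way were rgs20 (8.90 to 0.16 and 7.44 to 23.8) and HTRA2 (21.8 to 6.77 and 10.4 to 29.8). Gene length was taken as the smallest whole length that fits the FPKM values of a gene, a lower limit, with small RNAs left out. By that measure genes that fell in Mybx1 had a median length of 1232.5 nt, against 1629 nt for all genes counted there. Genes that fell in WT had a median of 1667 nt.

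A hypothesis is that Mybx1 embryos at 6 hpf stood at an earlier point of the WT course. The slope of the Mybx1 change on the WT change across genes was 0.24. Delayed development and a halt of development could both give it, and a share of unchanged egg RNA in the library could add to it. Without a WT library between 0 and 6 hpf delay and halt cannot be told apart. The genes aplnrb, isg15 and mxtx2, which stood above WT at 6 hpf, would be the ones to follow at intermediate stages.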
